A study of Mus musculus with 12 samples.

How the data were processed

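RNA sequencing was read from 1 table of the whole series, which holds a value per gene and library for 12 libraries of mouse osteoclasts. Groups, sex and batch were taken from the labels: male control, male Per2 knockout, female control and female Per2 knockout, each with a library in batch 1, 2 and 3. The series title names PER1 where the sample labels name Per2, and the sample labels were followed. The values are FPKM, made and deposited by the authors, fragments scaled by gene length and by a total for each library. Per the submitters' processing notes the tools were HISAT2 2.0.5, an aligner, and featureCounts 1.5.0-p3, which counts reads per gene, with the mouse build mm10. The strand setting, the deleted exons of Per2, the cells in which it was deleted and the exact denominator of the FPKM are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. The table held 55806 genes, 0 columns could not be mapped to a sample, and 1 line that held no gene was left out. The reference annotation, GENCODE M21, shared 52080 gene identifiers with it but only 1494 of them (2.9%) had the same position, so chromosomes are given and no coordinates.

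Each gene's FPKM was multiplied by its length in the table and divided by the step of 1 read, which gave whole numbers within 0.01 for 100.0% of the values above 0 and so the depth. The reads assigned to genes were 17747615, 17024720 and 17762190 in male controls, 17247517, 41145397 and 17141236 in male knockouts, 14979680, 17724559 and 13888150 in female controls and 17300267, 15239447 and 15339478 in female knockouts. The assigned reads were 0.936 to 0.948 of the authors' FPKM denominator in female controls, 1.007 to 1.017 in female knockouts and 1.075 to 1.105 in the male libraries. The scaling as deposited therefore differs between the groups, and the assigned reads were tried as a denominator. A floor of 3 reads was used where a gene had 0 reads, and it covers counting error only. Replicate libraries correlated at r = 0.986 to 0.992 and differed by 4.33 to 12.39 times the sampling noise (chi-square per degree of freedom), so none was counted as a copy of another.

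Genes with FPKM of at least 1 in at least 3 libraries were tested, 12102 in number, of which 10390 are protein coding. Limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) of all 12 libraries with the 4 group means, no block, a trend in the prior variance and 11 total degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The contrasts were knockout minus control in males, in females and averaged over the sexes, the female minus the male knockout effect, and female minus male in controls and in knockouts. Every adjusted p given for a gene is from this limma model unless another tool is named. The test, the samples, the 34 gene lists and the rule for named genes were fixed before the data were examined.

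By that rule Per2 is given first in every library. For the knockout contrasts, up to 10 protein-coding genes with the largest rise and up to 10 with the largest fall were named among those past the threshold with the same sign in every batch, filled to 5 by the smallest p where fewer passed and then given as values. For the interaction and the sex contrasts up to 5 in each direction were named, filled to 3. From each list up to 4 members with the smallest p were taken, and Per1, Per3, Cry1, Cry2, Arntl, Clock, Nr1d1, Nr1d2, Dbp, Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp, Ocstamp and Calcr were always followed. Predicted genes and pseudogenes were passed over, and some genes that the rule reached are not reported here, the next gene being taken.

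Gene lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 34 lists of a contrast, each with at least 4 tested members. They cover the clock, osteoclast differentiation, bone resorption, repressors of osteoclast formation, coupling factors, adhesion, inflammation, NF-kB, interferon, MHC class II, complement, lysosome, cell cycle, metabolism, stress, ribosome, mitochondrial, X-linked and Y-linked genes. Markers of other cells in bone marrow cultures form further lists: macrophages, dendritic cells, neutrophils, mast cells, B cells, T and NK cells, erythroid, stromal and stem cells. Camera with an estimated correlation and fry, which tests a list on its own, were alternatives. Fry does not compare a list with other genes. For single values an exact permutation test was used, and with 3 against 3 libraries its smallest two-sided p is 0.1.

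Libraries with the same number come from the same labelled batch, so the numbers pair the samples by label. The deviations from the group means of same-numbered libraries correlated at r = 0.02 on average over 18 pairs (−0.118 to 0.092). For libraries with different numbers the average was −0.01 over 36 pairs (−0.16 to 0.184), so these values show no shift shared within a batch. Fits with the batch as a replicate block were an alternative. Also fixed in advance were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, median-ratio rescaling alone and with the block, quantile normalization, rescaling to nuclear protein-coding genes, array quality weights, leaving out each library, and fits of only the 6 libraries of a sex or genotype. Chosen after seeing the data were limma voom on the recovered reads, the assigned reads as denominator, thinning to the smallest library, and leaving out genes that differed over 4-fold within a group.

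The procedure was tested on simulated data with known changes. For the male comparison (12110 genes) it recovered 73.8% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 92.3% of those changed 4-fold, and 5.1% of 177 calls were false. For the female comparison (12216 genes) it recovered 73.1%, 89.6% and 89.4%, and 7.2% of 181 calls were false. The simulation changed 67, 67 and 66 genes at these folds, balanced up and down and independent of each other. Its counts were made and scaled with the same denominator for each library. In the real female contrast limma called 6027 of 12102 genes, and the deposited scaling differs between the groups. The simulated shares of false calls therefore do not carry over to that contrast. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.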

Results

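Transcript levels were measured by RNA sequencing in osteoclasts, the multinucleated cells that resorb bone, in cultures labelled Per2 knockout and control. Per2 is a repressor of the circadian clock. The library names write the knockout as cKO, a usual abbreviation for a conditional knockout, and the labels do not say in which cells Per2 was deleted. The title of the series names PER1, a related clock repressor, while the sample labels name Per2, so which gene was deleted rests on the sample labels, which were followed. The cells were bone marrow monocytes of mice 8 to 12 weeks old, exposed to M-CSF and RANKL, the cytokines that drive osteoclast formation, and collected on day 4. Male control, male knockout, female control and female knockout groups had 3 libraries each, 1 from each of 3 labelled batches, which gave 12 libraries. The libraries held 13888150 to 17762190 reads assigned to genes, except male knockout replicate 2, which held 41145397. Values are FPKM, given as mean ± SD (n = 3). Fold changes are on the log2(FPKM + 1) scale, ± the limma standard error where given, a scale that understates the change of genes expressed at a low level. The labels call the replicates biological but do not say whether each came from its own mouse, so the p-values measure the spread between these libraries. The first principal component held 71.8% of the variance. On it the female controls lay between 49.93 and 52.24, the female knockouts between −1.99 and 5.62, and the 6 male libraries between −29.74 and −22.6.

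Per2 itself was expressed at a low level in every library. It was under 1 FPKM in each and so was not among the genes tested by limma. In males it was 0.579, 0.721 and 0.701 FPKM in the 3 control libraries and 0.466, 0.39 and 0.23 FPKM in the knockout libraries. The ratio of means was 0.54 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). In females it was 0.331, 0.53 and 0.368 FPKM in controls and 0.258, 0.204 and 0.589 FPKM in knockouts, a ratio of 0.86 (exact two-sided permutation p = 0.6). With labels exchanged within each sex, the exact permutation p over all 12 libraries was 0.065 among 400 regroupings, which can give 0.005 at the smallest. In limma with no filter on low values, the log2 change of Per2 was −0.29 in males (adjusted p = 0.852) and −0.07 in females (0.763). Over both sexes it was −0.18 (limma adjusted p = 0.205). The sources used here do not give the deleted exons, so a transcript that lacks them can still be counted, and these levels are a partial check of the genotype labels. The library labelled female knockout replicate 3 had the highest Per2 level of the 6 female libraries, against its label, and loss of Per2 was not shown in females. Groups and libraries are named by their labels throughout, and every direction given for female knockouts rests on those labels. Per1 was 4.39 ± 0.584 FPKM in male controls and 4.94 ± 0.608 in male knockouts, and 2.86 ± 0.27 in female controls and 3.61 ± 0.288 in female knockouts. The sex labels matched the data in 12 of 12 libraries. Xist, the RNA that silences the X chromosome, was at least 31.4 FPKM in the female libraries and 0.0 in the male libraries, and the 4 Y-linked genes were listed at 0 in every female library.

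The comparison of knockout and control within males addressed what differs in male osteoclasts labelled Per2 knockout. Of the genes of osteoclast function, Acp5, Ctsk and Mmp9 did not pass. Acp5, tartrate-resistant acid phosphatase, was 2010 ± 101 FPKM in male controls and 2020 ± 96.4 in male knockouts (log2 change 0.01, adjusted p = 0.994). Ctsk, the collagen-degrading cathepsin K, was 3910 ± 241 and 3880 ± 302 FPKM (−0.01, adjusted p = 0.992), and Mmp9, a matrix metalloproteinase, was 2430 ± 224 and 2300 ± 109 FPKM (−0.07, adjusted p = 0.925). The 28 tested genes of osteoclast differentiation and fusion had a median log2 change of 0.02 (camera adjusted p = 0.315), the 23 genes of bone resorption −0.01 (0.66), and the 16 clock and clock output genes 0.01 (0.931). Among the clock genes, Per1 was 0.14 higher on the log2 scale (adjusted p = 0.854), Cry1 differed by 0.00 and Clock by 0.04.

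Limma found 0 of 12102 genes changed in males, with 822 at an unadjusted p under 0.05 where 605 were expected with no difference. The genes with the smallest p were Trf and Cx3cr1. Trf, the iron carrier transferrin, was 18.2 ± 0.456 FPKM in controls and 12.6 ± 1.26 in knockouts (log2 change −0.51 ± 0.06, adjusted p = 0.0794). Cx3cr1, the fractalkine receptor of monocytes, was 35.9 ± 6.3 and 19.3 ± 2.2 FPKM (−0.85 ± 0.12, adjusted p = 0.0854). Limma voom on reads recovered from the FPKM values called 2 genes, which were these (adjusted p = 0.00226 for both). Both also passed with a pseudocount of 5 (0.0378 and 0.0452), an FPKM filter of 5 (0.0354 and 0.0375) and rescaling to nuclear protein-coding genes (0.0121 and 0.0075). They passed too with array quality weights (0.0198 for both), assigned reads as the denominator (0.0476) and thinning (0.0495). Neither passed with no filter (0.158 and 0.261), median-ratio rescaling (0.0704) or quantile normalization (0.0754). Both reached 0.431 without male control replicate 2. The values were 0.361 for both with only the 6 male libraries in the fit and 0.186 and 0.427 with the batch as a replicate block. The other genes named by rank of p were Gstm2, a glutathione transferase (−0.53, adjusted p = 0.144), and, all at adjusted p = 0.359, Igsf8 (−0.21), Gna12 (−0.22), Mycbp2 (0.26), Uba6 (0.22), Vwa5a (0.20), Luc7l3 (0.22) and Pou3f1. Pou3f1, a POU-domain transcription factor, was 2.42 ± 0.181 FPKM in controls and 3.95 ± 0.303 in knockouts (0.54). Leaving out 1 library gave 1 called gene in 4 cases, genes chosen after their values were seen. They were Trf without male knockout replicate 1 (adjusted p = 0.0194), Ifi208 without male knockout replicate 2 (log2 change −3.87, 0.0044), Wdfy1 without male knockout replicate 3 (−0.69, 0.00967) and Trbj1-2 without female knockout replicate 2 (−1.63, 0.0329).

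Of the 34 gene lists, 8 passed the camera test in males, 2 upward and 6 downward, and none of the 8 passed with an estimated correlation. The count was 5 without male control replicate 1 and 16 without male control replicate 3. Other splits of the male libraries, 3 against 3, passed a median of 7 lists and up to 21. The count of 8 therefore does not set knockout apart from control in males. The 20 genes of the NRF2 and oxidative stress list had a median log2 change of −0.09 (adjusted p = 1.32e-07, and adjusted p = 0.879 with an estimated correlation). Among them were Nqo1 (−0.42), Gclm, a subunit of an enzyme of glutathione synthesis (−0.26), Prdx1 (−0.23) and the ferritin chain Fth1 (−0.17). Interferon-stimulated genes had a median of 0.09 (adjusted p = 0.000923, and adjusted p = 0.925 with an estimated correlation), with Iigp1 at 0.36 and Gbp7 at 0.24. This call was absent without male control replicate 1 (adjusted p = 0.19). The 11 stromal, osteoblast and endothelial markers had a median of −0.96 and a mean of −0.73 (adjusted p = 0.000923, and adjusted p = 0.879 with an estimated correlation). Of these, Sparc was 5.11 ± 1.82 FPKM in controls and 1.00 ± 0.413 in knockouts (−1.59, adjusted p = 0.653). Col1a1, a chain of type I collagen, was 6.85 ± 2.79 and 1.59 ± 0.663 FPKM (−1.57, adjusted p = 0.686), Col3a1 was −1.29 and Bgn −0.96. Without the genes that differed over 4-fold within a group, the stromal list did not pass (adjusted p = 0.0672). Its median was −0.12 with no filter on low values and −1.69 by voom.

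The other lists that passed in males had smaller medians. NF-kB feedback and targets had a median of 0.06 (adjusted p = 0.0255, and adjusted p = 0.879 with an estimated correlation), with 0.242 without male control replicate 1 and 0.0834 without male knockout replicate 3. Monocyte and macrophage markers had −0.04 (0.0255, and adjusted p = 0.879 with an estimated correlation), with 0.433 without male control replicate 3 and 0.121 without male knockout replicate 2. Immediate early genes had −0.06 (0.0255, and adjusted p = 0.879 with an estimated correlation), with Egr1 at −0.43. They reached 0.114 without male control replicate 2, 0.0589 without male control replicate 3 and 0.202 without male knockout replicate 2. Cytosolic ribosomal proteins had −0.03 (0.0255, and adjusted p = 0.925 with an estimated correlation), with 0.755 and the opposite direction without male control replicate 3 and 0.339 without male knockout replicate 1. Cholesterol biosynthesis genes had −0.05 (0.0273, and adjusted p = 0.879 with an estimated correlation), with Mvk at −0.25. They reached 0.296 and 0.0597 without male control replicates 1 and 3, and 0.0959 and 0.206 without male knockout replicates 2 and 3. Adjusted over the list alone, single members passed in 4 of the 8 lists, all lower: 1 of NRF2 and oxidative stress, 1 of the macrophage markers, 2 of the immediate early genes and 1 of cholesterol biosynthesis. With array quality weights the median of the macrophage markers was 0.02 and that of the ribosomal proteins 0.00, the median of the immediate early genes was −0.03 with no filter, and that of the cholesterol genes −0.03 with a pseudocount of 5.

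The same comparison in females set the libraries labelled knockout against those labelled control, with no loss of Per2 shown by its level. All 38 tested interferon-stimulated genes rose, with a median log2 change of 2.74 (camera adjusted p = 1.84e-31). The count was also 38 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Irf7, a transcription factor that amplifies interferon production (chromosome 7), went from 14.0 ± 2.29 FPKM in female controls to 289 ± 46.6 in female knockouts, a 20.7-fold difference (log2 change 4.28 ± 0.13, adjusted p = 4.81e-09). Ifit3, which restricts viral replication (chromosome 19), went from 8.87 ± 0.907 to 195 ± 43.8 FPKM, 21.9-fold (4.29 ± 0.14, adjusted p = 5.75e-09). The ubiquitin-like Isg15 went from 22.4 ± 8.6 to 383 ± 77.2 FPKM, 17.0-fold (4.07 ± 0.21, adjusted p = 7.69e-08). Within the 3 labelled batches the mean of the list was 2.93, 2.71 and 2.87 higher in the female knockout library, against 0.21, 0.06 and 0.05 in males.

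Inflammatory cytokines and chemokines also rose, 25 of 32 with 2 lower (median 1.03, adjusted p = 1.64e-09). Their median was 0.50 with a pseudocount of 5, 1.55 with one of 0.1 and 1.67 by voom. The inflammatory counts were 27 and 2 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Cxcl10, a chemokine that draws T cells, went from 4.29 ± 1.29 to 95.1 ± 27.7 FPKM (4.17 ± 0.19, adjusted p = 3.9e-08). Ccl5 reached 326 ± 47.3 FPKM (3.89, adjusted p = 1.2e-08), and the acute-phase gene Saa3 went from 1.97 to 49.1 FPKM (4.09). Of the complement and Fc receptor genes, 13 of 16 rose and 2 fell (median 1.43, adjusted p = 4.45e-06). Complement counts were 13 and 2 adjusted over the list alone, with adjusted p = 0.185 with an estimated correlation. They included Fcgr1, the high-affinity IgG receptor, at 6.95 ± 2.02 and 135 ± 21.4 FPKM (4.11, adjusted p = 1.11e-08), Fcgr4 (2.83), C1qb, from 129 to 466 FPKM (1.84), and C3 (1.81). Other large rises were those of Ifit2 (4.28), Ms4a4c (4.25), Oasl1 (4.18) and Ifit3b (3.96).

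Markers of monocytes and macrophages rose for 14 of 21 genes and fell for 2 (median 0.59, adjusted p = 3.59e-05). Macrophage counts were 15 and 2 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Adgre1, which encodes the macrophage antigen F4/80, went from 83.4 ± 3.75 to 304 ± 29.8 FPKM (1.85, adjusted p = 1.26e-08), and the scavenger receptor Msr1 and the phagocytic receptor Mertk each rose by 0.96. Antigen presentation by MHC class II rose for 8 of 13 genes and fell for 1 (median 0.60, adjusted p = 0.00215), with Cd86 at 1.36, H2-Ab1 at 1.20 and H2-Eb1 at 1.11. MHC class II counts were 8 and 1 adjusted over the list alone, with adjusted p = 0.467 with an estimated correlation. Dendritic cell markers rose for 5 of 10 and fell for 1 (median 0.43, adjusted p = 0.0141), among them Ccl22 (1.70), Fscn1 (1.69) and Ccr7 (1.29). Dendritic counts were 5 and 1 adjusted over the list alone, with adjusted p = 0.325 with an estimated correlation. NF-kB feedback and targets rose for 15 of 25 and fell for 2 (median 0.30, adjusted p = 0.00274), with Cd40 at 2.05, Ier3 at 1.28 and Malt1 at −0.89. NF-kB counts were 15 and 2 adjusted over the list alone, with adjusted p = 0.185 with an estimated correlation. Immediate early genes rose for 15 of 20 and fell for 4 (median 0.66, adjusted p = 7.7e-05), led by Egr1, from 1.57 to 21.7 FPKM (3.14, adjusted p = 5.54e-09), Dusp1 (1.63) and Ier2 (1.45). Their counts were 15 and 4 adjusted over the list alone, with adjusted p = 0.185 with an estimated correlation.

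Genes of the osteoclast itself moved in both directions. Repressors of osteoclast formation rose for 15 of 19 genes and fell for 1 (median 0.57, adjusted p = 4.45e-06). Repressor counts were 17 and 1 adjusted over the list alone, with adjusted p = 0.111 with an estimated correlation. They included Zfp36, which destabilises cytokine mRNAs, from 18.0 to 61.2 FPKM (1.71, adjusted p = 4.81e-09), Id3 (1.33), Socs1 (1.08) and Pirb (0.57). Bone resorption genes rose for 13 of 23, with none lower (median 0.21, adjusted p = 0.000888, and 0.128 after quantile normalization). Their median was 0.03 after quantile normalization and with rescaling to nuclear protein-coding genes, and 0.11 with assigned reads as the denominator. Resorption counts were 13 and 0 adjusted over the list alone, with adjusted p = 0.525 with an estimated correlation. Among them were the creatine kinase Ckb, from 719 to 1230 FPKM (0.77, adjusted p = 9.07e-05), the chloride transporter Clcn7 (0.58, adjusted p = 9.39e-06), Plekhm1 (0.45) and Mmp14 (0.38). Acp5 went from 1930 ± 152 to 2510 ± 252 FPKM (0.37 ± 0.08, adjusted p = 0.00227) and Mmp9 from 2330 ± 128 to 3150 ± 289 FPKM (0.43 ± 0.08, adjusted p = 0.00115). Both calls were lost after quantile normalization (Acp5 0.03 and adjusted p = 0.832, Mmp9 0.15 and 0.117) and with no filter on low values (0.0708 and 0.0621), and that of Acp5 also with rescaling to nuclear protein-coding genes (0.19, 0.0679). Ctsk was 4370 ± 172 and 5020 ± 678 FPKM (0.19, adjusted p = 0.104).

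Genes of osteoclast differentiation and fusion rose for 11 of 28 and fell for 5, the same counts adjusted over the list alone. Their median of 0.13 became −0.05 after quantile normalization and with rescaling to nuclear protein-coding genes, and the list did not pass (adjusted p = 0.162). Its members with the smallest p were Fcer1g (1.05), Cd47 (0.70), Fos (0.67) and Mitf (−0.41). Nfatc1, the transcription factor required for osteoclast formation, was at −0.19 in female knockouts on the log2 scale (adjusted p = 0.0378). This call was lost without female control replicates 1, 2 or 3 (adjusted p = 0.112, 0.0679 and 0.056), without female knockout replicates 1 or 3 (0.11 and 0.132) and with median-ratio rescaling (0.0631). The fusion gene Ocstamp was 0.24 higher (adjusted p = 0.0332), a call lost without female control replicates 2 or 3 (0.0915 and 0.0869) or female knockout replicates 2 or 3 (0.128 and 0.0538) and after quantile normalization (0.368). Dcstamp (0.14, adjusted p = 0.41) and Calcr, the calcitonin receptor (0.21, 0.147), did not pass.

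Coupling factors secreted by osteoclasts rose for 6 of 10 and fell for 1 (median 0.37, adjusted p = 0.008, and 0.0571 with an FPKM filter of 5), with Cxcl16 at 1.24 and Tgfb1 at 0.59. Coupling factor counts were 6 and 1 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Adhesion and podosome genes rose for 17 of 30 and fell for 5 (adjusted p = 0.00988, and 0.565 after quantile normalization), with a median of 0.17 that became −0.02 with rescaling to nuclear protein-coding genes. Adhesion counts were 17 and 5 adjusted over the list alone, with adjusted p = 0.47 with an estimated correlation. Actb was at 0.67, Rac2 at 0.53, Ptk2b at 0.44 and Arpc2 at 0.38. Lysosomal enzymes and membrane proteins rose for 24 of 27 (median 0.40, adjusted p = 7.57e-10). Lysosomal counts were 25 higher and 1 lower adjusted over the list alone, with adjusted p = 0.111 with an estimated correlation. Npc2, which exports cholesterol from lysosomes, went from 177 to 356 FPKM (1.01), and Psap (0.70), Ctsb (0.66) and Ctsz (0.64) rose with it.

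Cell cycle genes fell in the female knockouts, 27 of 36 with none higher (median −0.53, adjusted p = 7.57e-10). Cell cycle counts were 30 lower and 1 higher adjusted over the list alone, with adjusted p = 0.185 with an estimated correlation. Mki67, a marker of dividing cells, went from 41.6 ± 0.94 to 21.9 ± 0.861 FPKM (−0.90, adjusted p = 1.42e-07), and Cdk1 (−0.89), Ccna2 (−0.82) and Ccnb2 (−0.56) fell with it. Of the cytosolic ribosomal protein genes 22 of 40 fell and 2 rose (median −0.17, adjusted p = 0.000888), with Rpl5 at −0.47, Rpsa at −0.36 and Rpl3 at −0.32. The ribosomal median was −0.35 after quantile normalization, −0.36 with rescaling to nuclear protein-coding genes and −0.27 with assigned reads as the denominator. Ribosomal counts were 22 and 2 adjusted over the list alone, with adjusted p = 0.618 with an estimated correlation. The protein-coding genes named for large falls were led by Mmp12, a macrophage elastase, from 176 ± 20.6 to 30.8 ± 2.39 FPKM (−2.47 ± 0.28, adjusted p = 2.99e-05). The chemokine Cxcl14 went from 12.5 to 2.87 FPKM (−1.80), and the integrin Itgax from 35.3 ± 2.91 to 10.7 ± 0.722 FPKM (−1.63, adjusted p = 7.91e-07). Egr2 (−1.57), Cd79a (−1.57), Vsig8 (−1.42), Emp2 (−1.39), Gpc1 (−1.37) and Mycl (−1.28) followed. Sumo2, a protein modifier, was 64.4 ± 9.41 FPKM in controls and 13.6 ± 12.0 in knockouts (−2.47 ± 0.77, adjusted p = 0.0206). This call was lost without female control replicate 1 (0.0507) or 3 (0.0554) or female knockout replicate 1 (0.0771) or 2 (0.0637).

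Markers of other cells moved with these groups. B cell and plasma cell markers fell for 8 of 11 (median −0.94, adjusted p = 0.00337, and 0.078 with an FPKM filter of 5), among them Ms4a1 (−0.94) and Blk (−1.05). The B cell count was 8 adjusted over the list alone, with adjusted p = 0.525 with an estimated correlation. X-linked genes that escape inactivation fell for 6 of 9 (median −0.34, adjusted p = 0.008, and 0.0868 with rescaling to nuclear protein-coding genes). Their count was 6 adjusted over the list alone, with adjusted p = 0.166 with an estimated correlation. Xist went from 55.0 ± 1.57 to 35.0 ± 3.15 FPKM (−0.64, adjusted p = 5.86e-06), the helicase Ddx3x from 136 to 86.4 FPKM (−0.64), and Eif2s3x fell by 0.45. The lists of further cell types did not pass. Neutrophil markers were 4 higher and 1 lower of 18 (0 and 0 adjusted over the list alone), with a median of 0.18, or −0.01 with rescaling to nuclear protein-coding genes (adjusted p = 0.264). Mast cell, basophil and eosinophil markers were lower for 3 of 12 (2 adjusted over the list alone, median −0.36, adjusted p = 0.206). T and NK cell markers were higher for 1 of 6 (1 adjusted over the list alone, median 0.10, adjusted p = 0.643) and erythroid and megakaryocyte markers for 1 of 8 (1 adjusted over the list alone, median −0.19, adjusted p = 0.865). Stromal, osteoblast and endothelial markers were 1 higher and 1 lower of 11 (1 and 0 adjusted over the list alone, median −0.29, mean −0.04, adjusted p = 0.741). Stem and progenitor markers were 1 higher and 2 lower of 9 (1 and 1 adjusted over the list alone, adjusted p = 0.741), with a median of 0.03 and a mean of 0.36, and medians of −0.05 with assigned reads as the denominator and −0.10 with rescaling to nuclear protein-coding genes. The list of 4 Y-linked genes, listed at 0 in every female library, gave an adjusted p of 0.967.

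Metabolic and stress genes changed in part. Nuclear-encoded oxidative phosphorylation genes rose for 20 of 42 and fell for 1 (adjusted p = 0.00988), with a median of 0.16 that became −0.04 after quantile normalization and −0.03 with rescaling to nuclear protein-coding genes. Their counts were also 20 and 1 adjusted over the list alone, with adjusted p = 0.663 with an estimated correlation. This call was lost without female knockout replicate 2 (adjusted p = 0.106) and with assigned reads as the denominator (0.102). Cox5b (0.45) and Cox4i1 (0.34) were among the members that rose. Glycolysis and hypoxia genes rose for 9 of 25 (adjusted p = 0.0302), with a median of 0.15 that became −0.01 after quantile normalization and with rescaling to nuclear protein-coding genes, and with Pfkfb3 at 0.88 and Hk1 at 0.52. The glycolysis count was 9 adjusted over the list alone, with adjusted p = 0.663 with an estimated correlation. The list did not pass without female control replicate 2 (0.0518) or 3 (0.0831) or female knockout replicate 1 (0.0567) or 2 (0.0625).

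The unfolded protein and integrated stress response list rose for 14 of 25 and fell for 5 (median 0.22, adjusted p = 0.0226, and 0.0705 after quantile normalization), with Nupr1 at 1.59, Sdf2l1 at 0.95 and the chaperone Hspa5 at 0.51. Stress response counts were 16 and 5 adjusted over the list alone, with adjusted p = 0.366 with an estimated correlation. Of the heat shock proteins 6 of 11 fell and 1 rose, also adjusted over the list alone, with Hsp90aa1 at −0.70 and Hspd1 at −0.64. That list had a median of −0.17, or −0.36 with rescaling to nuclear protein-coding genes, and did not pass (adjusted p = 0.0649, and 0.0383 with the batch as a replicate block). Of the NRF2 and oxidative stress genes 6 of 20 rose and 11 fell, also adjusted over the list alone (median −0.19, adjusted p = 0.211), with Fth1 at 1.15 and the thioredoxin reductase Txnrd1 at −0.91. The NRF2 median became −0.38 with rescaling to nuclear protein-coding genes. LXR targets and lipid handling genes rose for 8 of 18 and fell for 6 (9 and 6 adjusted over the list alone, median 0.20, adjusted p = 0.264), with Nr1h3 at 1.53, Abca1 at 0.92 and Lpl at −0.91. The LXR median became 0.03 with rescaling to nuclear protein-coding genes. Cholesterol biosynthesis genes rose for 6 of 20 (4 adjusted over the list alone, adjusted p = 0.264), with Insig1 at 0.43. Their median of 0.06 became −0.02 with assigned reads as the denominator and −0.09 with rescaling to nuclear protein-coding genes.

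Of the mitochondrially encoded genes, 7 of 15 fell and 2 rose (8 and 2 adjusted over the list alone, median −0.32, adjusted p = 0.153). The mRNA mt-Nd4 went from 1530 to 953 FPKM (−0.69) and the ribosomal RNA mt-Rnr1 from 209 to 549 FPKM (1.39, adjusted p = 1.93e-08). Mitochondrially encoded genes took 2.82 to 3.12% of the assigned reads in female controls, 2.12 to 2.51% in female knockouts and 1.47 to 1.75% in the male libraries. Clock and clock output genes rose for 2 of 16 and fell for 3 (1 and 3 adjusted over the list alone, adjusted p = 0.832), with a median of 0.01, or −0.07 with assigned reads as the denominator and −0.14 with rescaling to nuclear protein-coding genes. Bhlhe40, a clock-linked repressor, fell by 0.30 (adjusted p = 0.00108) and Nfil3 rose by 0.46 (0.0149). Per1 was at 0.26 (adjusted p = 0.0446), a call lost without female control replicate 1 (0.144) or 2 (0.0796), female knockout replicate 2 (0.0816) or 3 (0.14), male control replicate 1 (0.0567) or male knockout replicate 3 (0.0585). Clock was at −0.17 (adjusted p = 0.0264), a call lost without female control replicate 2 (0.081) or 3 (0.0731) or female knockout replicate 1 (0.0945) or 3 (0.0504). Cry1 (0.04), Cry2 (0.01), Arntl (−0.08), Nr1d1 (−0.04), Nr1d2 (−0.09) and Dbp (0.09) did not pass.

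In all, limma called 6027 of 12102 genes (49.8%) in females, 3018 higher and 3009 lower in the knockouts. More than 1 log2 unit of change was seen for 421 genes that rose and 62 that fell. By camera 20 of 34 lists passed, 16 upward and 4 downward, and none of these with an estimated correlation. The share of called genes that were higher, 50.1%, moved to 33.7% with assigned reads as the denominator, 23.0% with rescaling to nuclear protein-coding genes and 41.1% after quantile normalization. The median of all genes, −0.01 as deposited, was −0.10, −0.18 and −0.05 under these scalings. The interferon-stimulated genes rose for 38, 36 and 38 of the tested members under them, and the cell cycle genes fell for 31, 32 and 31. Medians of further lists that passed also moved by over 1.5 times. With rescaling to nuclear protein-coding genes they were 0.22 for lysosomal, 0.12 for NF-kB and 0.04 for stress response genes, and with a pseudocount of 5 they were 0.18 for coupling factors, 0.31 for repressors, −0.21 for the X-linked genes and −0.43 for B cell markers (−1.45 by voom). With no filter they were 0.36 for macrophage and 0.06 for dendritic cell markers, the latter 1.69 with an FPKM filter of 5. Reads of nuclear ribosomal RNA genes were 0.39 to 0.45% of the assigned reads in female controls and 0.56 to 0.71% in female knockouts, beside 0.34 to 0.44% in male controls and 0.35 to 0.63% in male knockouts. Off the X and Y chromosomes, 5083 genes were called both in this contrast and between the sexes in controls. Of them 5067 (99.7%) had opposite signs, with a female knockout change at a median of 0.72 of the sex difference. Both contrasts use the same female control libraries, so they are not independent results.

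**Figure D1:**
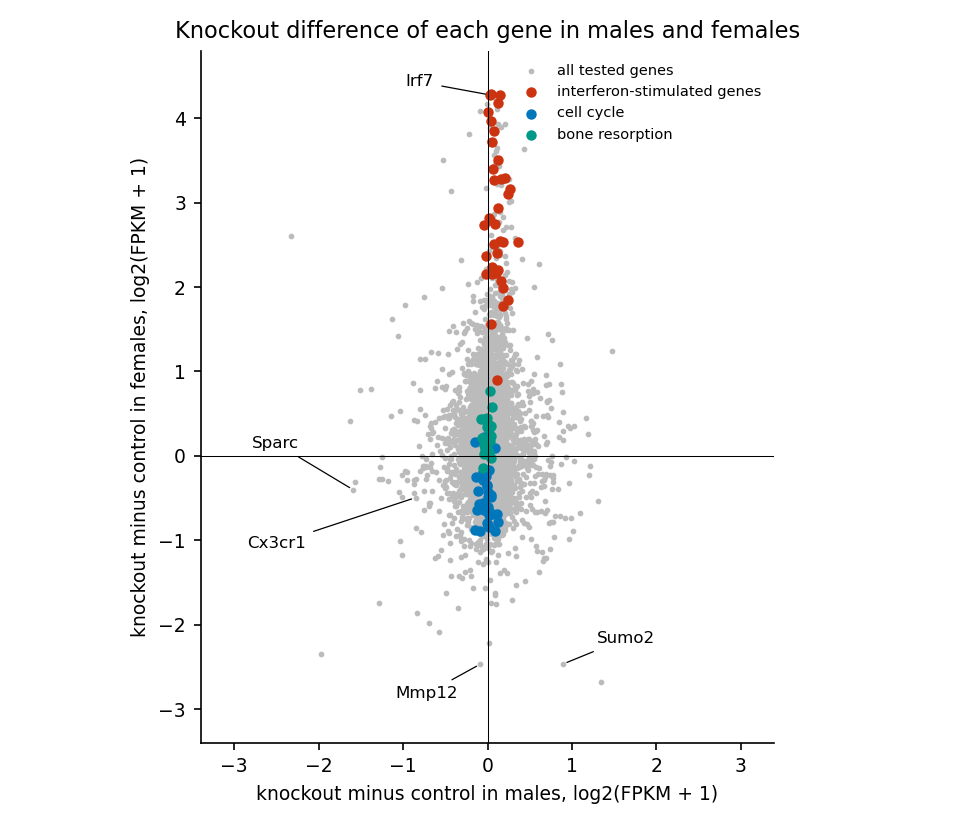
Each point is 1 tested gene, with its knockout minus control difference on the log2(FPKM + 1) scale in males on the x axis and in females on the y axis (red, interferon-stimulated genes, blue, cell cycle, green, bone resorption, whose rise in females was not called as a list after quantile normalization, and grey, all tested genes). Irf7 lies at 4.28 and Mmp12 at −2.47 in females, while Cx3cr1 lies at −0.85 in males.

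**Figure D2:**
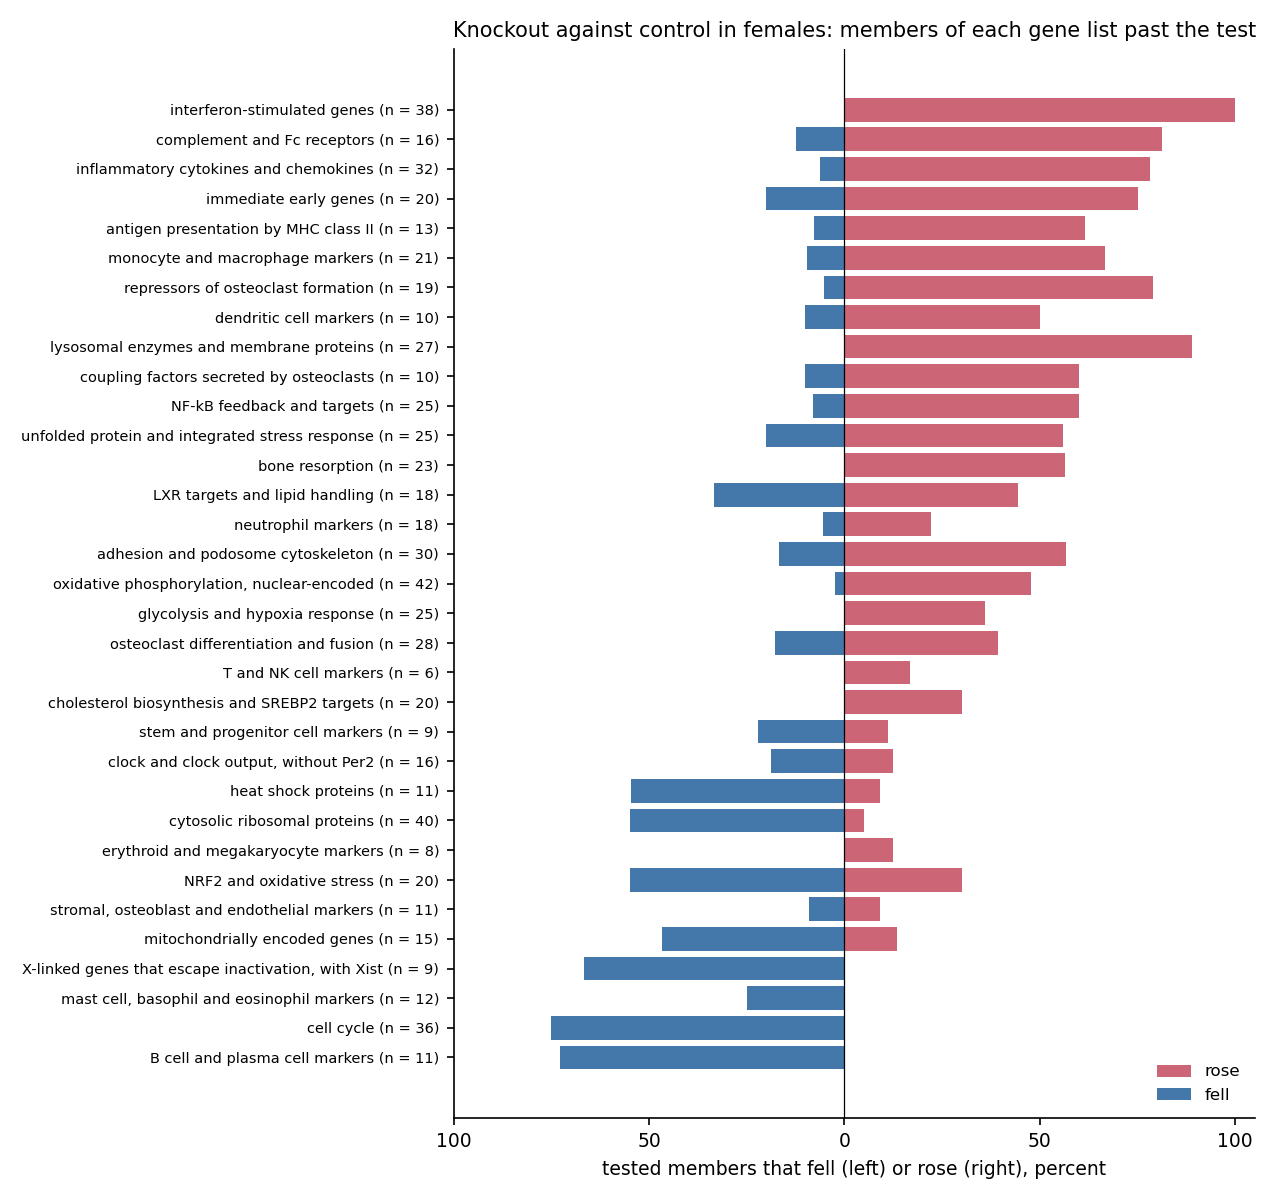
For each of 33 gene lists, the bars give the percent of tested members that rose or fell in female knockouts against female controls at an adjusted p under 0.05. All 38 interferon-stimulated genes rose and 27 of 36 cell cycle genes fell, and under other scalings the list medians of osteoclast differentiation, oxidative phosphorylation, glycolysis, adhesion, neutrophil, cholesterol, clock and stem cell genes changed sign.

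The difference between the knockout effects of the sexes was tested as an interaction, female minus male. The interferon-stimulated genes had a more positive effect in females for 38 of 38 (median difference 2.72, adjusted p = 3.3e-36). The count was 38 adjusted over the list alone, with adjusted p = 0.156 with an estimated correlation. Irf7 differed by 4.25 (adjusted p = 2.07e-07), Ifit3 by 4.25 (2.84e-07), Ms4a4c by 4.19 (8.03e-07) and Cxcl10 by 4.18 (1.63e-06). The effect was more positive in females for 23 of 27 lysosomal genes (24 adjusted over the list alone, median 0.44, adjusted p = 1.46e-10, and adjusted p = 0.149 with an estimated correlation). It was more positive for 13 of 21 macrophage markers and more negative for 1 (13 and 1 adjusted over the list alone, median 0.57, adjusted p = 1.07e-06, and adjusted p = 0.149 with an estimated correlation). It was more negative for 25 of 36 cell cycle genes and more positive for 1 (27 and 1 adjusted over the list alone, median −0.51, adjusted p = 1.92e-09, and adjusted p = 0.224 with an estimated correlation). Mmp12 (−2.38, adjusted p = 0.000894) and Itgax (−1.72, 1.91e-05) also had a more negative effect in females.

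For Mmp9 the knockout effects of the sexes differed by 0.51 (adjusted p = 0.006, but 0.153 after quantile normalization and 0.0515 with rescaling to nuclear protein-coding genes). For Ctsk they differed by 0.20 (0.252), for Nfatc1 by −0.24 (0.0771) and for Per1 by 0.12 (0.54). Acp5 differed by 0.37 (adjusted p = 0.025), a call lost after quantile normalization (0.69) and without male control replicate 1 (0.0567), male knockout replicate 1 (0.051) or 3 (0.0585), or female control replicate 2 (0.0609) or 3 (0.0597). Bone resorption genes had a more positive effect in females for 11 of 23 (11 adjusted over the list alone, median 0.27, adjusted p = 0.00116). That list gave adjusted p = 0.54 with an estimated correlation, and 0.134 with a median of 0.08 after quantile normalization. The lysosomal median of 0.44 became 0.25 with rescaling to nuclear protein-coding genes. Over all genes, limma called 4185 interactions, 2165 positive and 2020 negative. The positive share of 51.7% moved to 34.4%, 22.6% and 41.7% with assigned reads as the denominator, rescaling to nuclear protein-coding genes and quantile normalization. By camera 19 lists passed, 15 upward and 4 downward, none with an estimated correlation. Across 11706 genes, which are not independent replicates, the knockout effects in males and females had r = 0.06 and rho = 0.06. In absolute value 6 of 10 relabelings gave a correlation as large, up to 0.13.

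**Figure D3:**
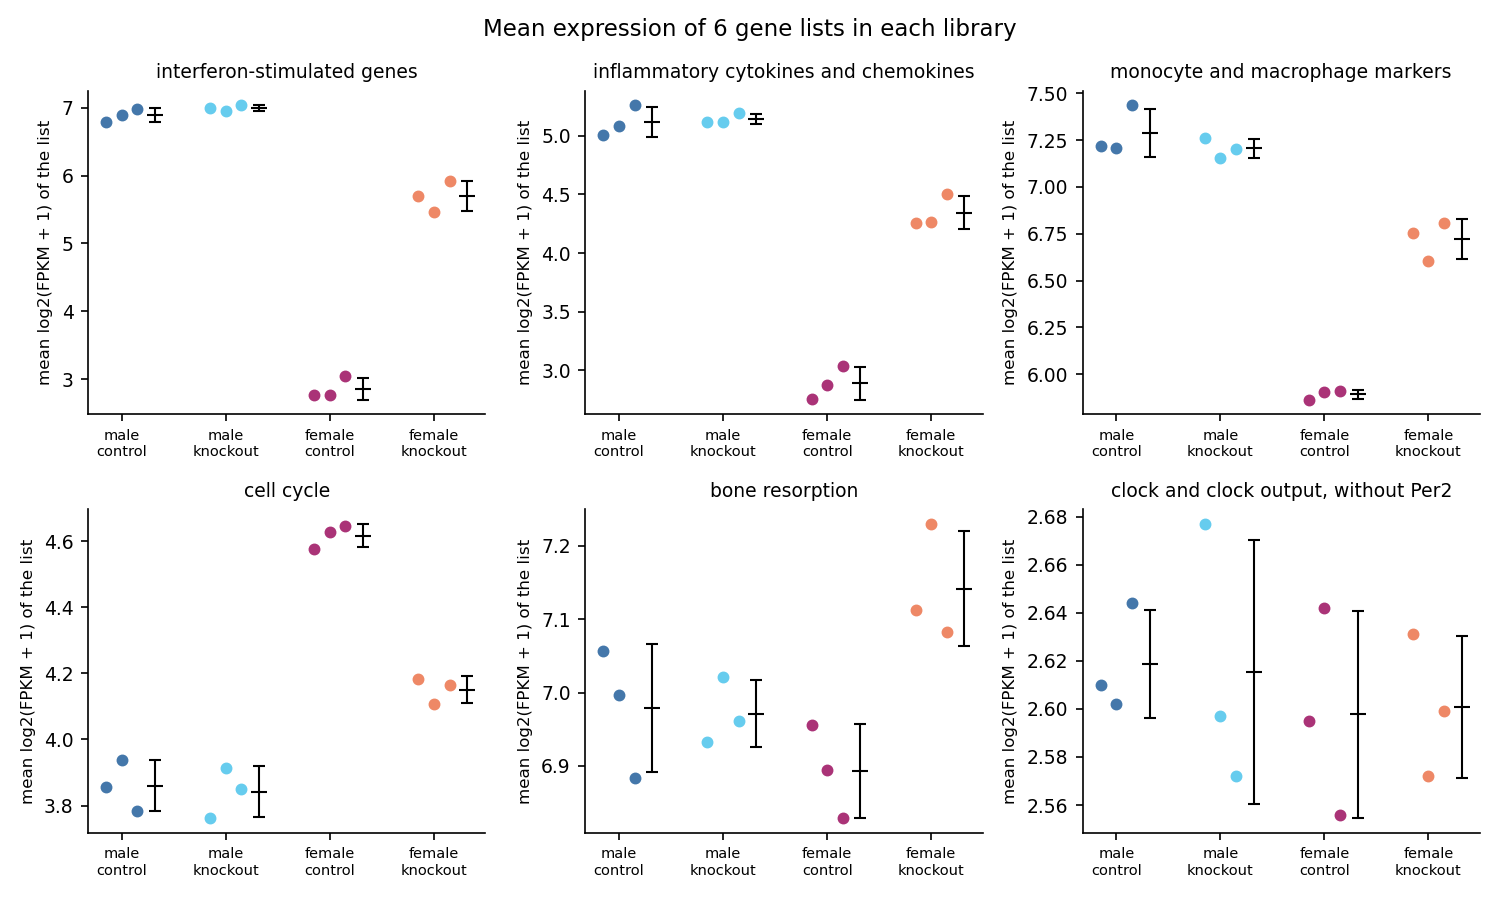
Each point is 1 library's mean log2(FPKM + 1) over the tested members of a list (y axes do not start at 0), with bars for the group mean ± SD (n = 3), for interferon-stimulated, inflammatory, macrophage, cell cycle, bone resorption and clock genes. The interferon list differed between female knockout and control libraries by 2.71 to 2.93 within the 3 batches, while the medians of bone resorption and clock genes between control females and males, −0.06 and −0.05, became 0.25 and 0.03 after quantile normalization.

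The knockout effect averaged over both sexes compared the libraries labelled knockout and control in male and female cells together. In males the list medians were 0.09 for interferon-stimulated, 0.04 for inflammatory, −0.01 for cell cycle and −0.01 for bone resorption genes. In females they were 2.74, 1.03, −0.53 and 0.21, so for these lists the values over both sexes come mainly from the female libraries. The 38 interferon-stimulated genes were all higher (median 1.42, adjusted p = 2.9e-37). Here too the count was 38 adjusted over the list alone, with adjusted p = 0.158 with an estimated correlation. Ifit2 was 2.22 higher (adjusted p = 2.95e-07), Oasl1 2.15 (1.62e-07), Fcgr1 2.11, Slfn4 2.03 and Acod1, which makes itaconate, 1.88 (1.34e-07). Siglec1 (1.78), Usp18 (1.75), Cmpk2 (1.73), Ifi205 (1.72) and Ifi44 (1.72) followed. Cx3cr1 fell by 0.67 ± 0.08 (adjusted p = 0.000112), with 22.9 ± 1.8 and 15.9 ± 1.11 FPKM in female controls and knockouts beside 35.9 ± 6.3 and 19.3 ± 2.2 in males. Vsig8 (−0.93, adjusted p = 5.38e-06), Serinc2 (−0.72, 1.24e-05), Rgs16 (−0.65), Angptl2 (−0.63) and Cd207 (−0.62) fell as well.

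Cell cycle genes fell for 27 of 36 over both sexes (28 adjusted over the list alone, median −0.28, adjusted p = 9.51e-11, and adjusted p = 0.168 with an estimated correlation). Inflammatory genes rose for 23 of 32 and fell for 2 (26 and 2 adjusted over the list alone, median 0.51, adjusted p = 1.11e-09, and adjusted p = 0.158 with an estimated correlation). The NRF2 and oxidative stress list fell for 11 of 20 and rose for 3 (13 and 4 adjusted over the list alone, median −0.13, adjusted p = 0.0246). This list gave adjusted p = 0.538 with an estimated correlation, and 0.0793 with rescaling to nuclear protein-coding genes. Bone resorption genes rose for 11 of 23 (11 adjusted over the list alone, median 0.10, adjusted p = 0.00299), with adjusted p = 0.538 with an estimated correlation and 0.208 after quantile normalization. Clock genes had a median of 0.00, or −0.08 with rescaling to nuclear protein-coding genes (1 of 16 higher and 2 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.799). Ctsk was 0.09 higher (adjusted p = 0.312). Acp5 was 0.19 higher (0.0207), a call that became −0.01 after quantile normalization and was lost without female control replicate 2 (0.0517) or 3 (0.0507). Limma called 4188 genes, 2246 higher and 1942 lower, a higher share of 53.6% that moved to 34.4%, 24.1% and 42.2% with assigned reads as the denominator, rescaling to nuclear protein-coding genes and quantile normalization. Camera passed 20 lists, 14 upward and 6 downward, none with an estimated correlation. The inflammatory median over both sexes was 0.26 with a pseudocount of 5 and 0.84 by voom, and with rescaling to nuclear protein-coding genes that of bone resorption genes was 0.01 and that of the NRF2 list −0.22. The effect over both sexes is the mean of a female and a male effect that differed for 4185 genes.

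Control osteoclasts of the sexes were compared as female minus male. This contrast shares its female libraries with the knockout comparison in females, so their results are not independent. The interferon-stimulated genes were lower in female than in male controls for 38 of 38 (38 adjusted over the list alone, median −3.63, adjusted p = 5.76e-26, and adjusted p = 0.17 with an estimated correlation). Ifit1bl1 was 189 ± 51.0 FPKM in male controls and 1.27 ± 0.0796 in female controls, 149-fold higher in males (log2 difference −6.36, adjusted p = 5.78e-10). Ifit2 was 438 ± 44.2 and 5.28 ± 1.14 FPKM, 82.8-fold (−6.13, adjusted p = 2.36e-10), and the chemokine Ccl7 was 102 ± 8.14 and 0.537 ± 0.555 FPKM (−6.13, adjusted p = 2.33e-08). Ifit3 (−6.08) and Ifit3b (−6.07) were close to these. The mean of the list was −4.01, −4.13 and −3.94 in females against males within the 3 batches.

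Macrophage markers were lower in female controls for 18 of 21 (19 adjusted over the list alone, median −1.19, adjusted p = 6.13e-08, and adjusted p = 0.0773 with an estimated correlation). Inflammatory genes were lower for 30 of 32 and higher for 2 (30 and 2 adjusted over the list alone, median −1.73, adjusted p = 7.49e-10, and adjusted p = 0.15 with an estimated correlation). Lysosomal genes were lower for 24 of 27 (24 adjusted over the list alone, median −0.57, adjusted p = 3.91e-09, and adjusted p = 0.0723 with an estimated correlation). Cell cycle genes were higher in female controls for 32 of 36 and lower for 2 (32 and 2 adjusted over the list alone, median 0.85, adjusted p = 2.49e-11, and adjusted p = 0.17 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 31 of 40 (31 adjusted over the list alone, median 0.23, adjusted p = 3.66e-06, and adjusted p = 0.428 with an estimated correlation). In controls the macrophage median was −0.74 with no filter, the inflammatory −0.94 with a pseudocount of 5, the lysosomal −0.24 with rescaling to nuclear protein-coding genes and the ribosomal 0.59 after quantile normalization. Single genes higher in female controls included Mmp12 (2.19, adjusted p = 3.73e-05), Itgax, at 8.25 ± 0.765 FPKM in males and 35.3 in females (1.97, adjusted p = 6.5e-08), Serinc2 (1.88), Mycl (1.84) and Nfatc1, at 35.0 ± 3.09 and 54.5 ± 1.88 FPKM (0.63, adjusted p = 1.27e-05).

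Per1 was lower in female than in male controls (−0.48, adjusted p = 0.00117) and Clock higher (0.27, 0.00142). The median of the clock list was −0.05, or 0.11, 0.20 and 0.03 with assigned reads as the denominator, rescaling to nuclear protein-coding genes and quantile normalization (adjusted p = 0.923). Acp5 (−0.06, adjusted p = 0.537) and Mmp9 (−0.05, 0.586) did not differ past the threshold as deposited but were higher in females after quantile normalization (0.25 and 0.33) and with rescaling to nuclear protein-coding genes (0.28 and 0.29). Limma called 7295 genes (60.3%), 3574 higher and 3721 lower in females. The higher share of 49.0% moved to 69.7%, 78.9% and 60.9% with assigned reads as the denominator, rescaling to nuclear protein-coding genes and quantile normalization, and the median of all genes moved from 0.00 to 0.18, 0.29 and 0.09. By camera 18 lists passed, 4 higher and 14 lower, none with an estimated correlation. The lists not passed in that setting include the 4 Y-linked genes. Their summed level was 0.0 FPKM in every female library and at least 36.4 in the male libraries. The setting thus missed a known difference, and a list that did not pass with it is not shown to be unchanged.

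Knockout osteoclasts of the sexes were compared in the same way. The interferon-stimulated genes were lower in female than in male knockouts for 38 of 38 (38 adjusted over the list alone, median −1.33, adjusted p = 1.19e-25, and adjusted p = 0.202 with an estimated correlation). Ifit1bl1 was 198 FPKM in male and 27.3 in female knockouts (−2.84, adjusted p = 7.46e-06), and Ccl7 (−2.42) and Slfn4 (−2.40) were also lower. Cell cycle genes were higher in females for 28 of 36 and lower for 1 (31 and 1 adjusted over the list alone, median 0.36, adjusted p = 4.22e-12, and adjusted p = 0.202 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were higher for 26 of 42 (30 adjusted over the list alone, median 0.20, adjusted p = 2.74e-10, and adjusted p = 0.279 with an estimated correlation). Bone resorption genes were higher in females for 10 of 23 and lower for 2 (13 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.00142, and adjusted p = 0.462 with an estimated correlation). The median of resorption genes was 0.35 with rescaling to nuclear protein-coding genes, and that of oxidative phosphorylation genes 0.36 after quantile normalization. Among the resorption genes were Mmp9 (0.45, adjusted p = 0.0017), Ctsk (0.36, 0.0104) and Acp5 (0.31, 0.0117), each lost with no filter on low values (0.0758, 0.358 and 0.186). The genes named for their excess in females included the quinone reductase Nqo1 (1.41, adjusted p = 4.49e-05), Egr1, at 8.18 FPKM in males and 21.7 in females (1.30, adjusted p = 1.1e-05), and the scavenger receptor Marco, at 80.9 and 173 FPKM (1.09, adjusted p = 0.00546).

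The Y-linked genes were lower in female than in male knockouts for 4 of 4, also adjusted over the list alone (median −3.18, adjusted p = 5.55e-08, and adjusted p = 0.0124 with an estimated correlation). The X-linked genes that escape inactivation were higher for 6 of 9, also adjusted over the list alone (median 0.32, adjusted p = 9.3e-06, and adjusted p = 0.0309 with an estimated correlation). With a pseudocount of 5 these medians were −1.46 and 0.21, and the Y-linked median was −10.64 by voom. These were the 2 of 21 passing lists that held with an estimated correlation. Limma called 4054 genes, 1586 higher and 2468 lower in females, a higher share of 39.1% that moved to 66.8%, 73.9% and 57.3% with assigned reads as the denominator, rescaling to nuclear protein-coding genes and quantile normalization. Across 11706 genes, which are not independent replicates, the sex difference in knockouts followed that in controls with r = 0.72, rho = 0.62 and a slope of 0.34. The largest absolute r among the other 9 of 10 relabelings was 0.55. Each of those mixed the sexes unequally on both sides and so kept a part of the sex difference. The 0.55 is therefore not a level reached with no sex difference.

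**Figure D4:**
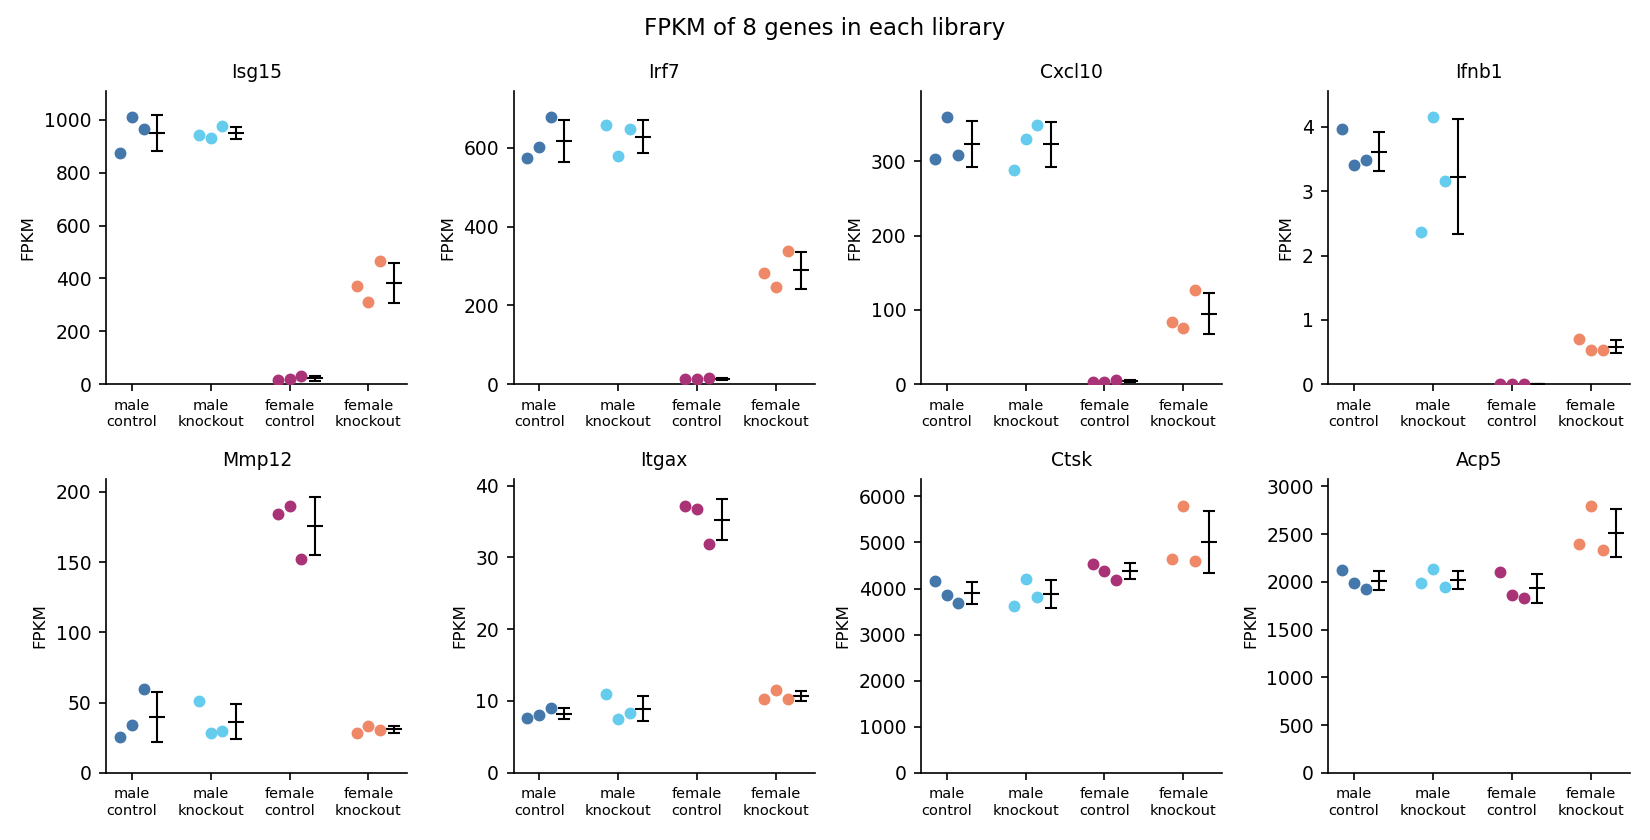
Each point is 1 library's FPKM for Isg15, Irf7, Cxcl10, Ifnb1, Mmp12, Itgax, Ctsk and Acp5, with bars for the group mean ± SD (n = 3). Irf7 lies at 14.0 ± 2.29 in female controls, 289 ± 46.6 in female knockouts and 618 ± 53.7 in male controls, and Acp5 at 1930 ± 152, 2510 ± 252 and 2010 ± 101, with the rise of Acp5 in females no longer called after quantile normalization (log2 change 0.03).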

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

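The tests of macrophage-like cells, exchanged labels, stromal cells and splits were chosen after the results were seen, and the ranges given with the stromal test were added after its value was known. The test of Sumo2 reads shared with other genes was set before its result.

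The knockout effect differed between the sexes for 4185 genes and 19 gene lists by the interaction test, none of the lists with an estimated correlation. The interferon-stimulated genes had a median difference of 2.72, with Irf7 at 4.25, Ifit3 at 4.25, Ms4a4c at 4.19 and Cxcl10 at 4.18. More negative in females were Mmp12 (−2.38), the mast cell protease Mcpt8 (−1.91), Prss34 (−1.90) and Itgax (−1.72). Mcpt8 (adjusted p = 0.0411) lost its call without male control replicate 1 (0.0869) or 2 (0.0878), male knockout replicate 1 (0.0733), female control replicate 1 (0.0549) or 3 (0.0897), or female knockout replicates 1, 2 or 3 (0.0622, 0.0854 and 0.0554), and Prss34 with no filter on low values (0.0639). Ifi208 differed by 4.94 (adjusted p = 0.0169, and 0.0533 with a pseudocount of 5, 0.0558 with no filter and 0.0683 by voom). It was 0.0483, 26.0 and 0.158 FPKM in the male knockout libraries and 0, 0.0712 and 0.244 in the female controls, against 10.9 to 25.9 in male controls.

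The first pattern is the low level of interferon-stimulated genes in the female controls, a group shared by the knockout effect in females and the sex difference in controls. The list was also lower in female than in male knockouts, a comparison without the female controls. The values do not settle which group departs from the others, and a raised level in the male cultures was not tested. Each labelled batch held 1 library of every group, and within them the list mean differed between female knockout and control by 2.71 to 2.93 on the log2 scale, which restates the group difference. For a smaller share of macrophage-like cells, only 4 of 38 interferon genes lay below the lowest macrophage marker, Fcgr1 (−5.55). The bound set against that explanation was therefore not met, but this rests on 1 marker. Below the second-lowest, Marco (−2.95), lay 31 interferon genes, and 35 lay below the third-lowest, Ly6c2 (−2.44). The macrophage median was −1.19, with Cd36 at −0.17, and the interferon median −3.63. The fall of a marker need not equal the change in the share of such cells, since other cells in the culture can express it too. These values therefore do not decide whether a smaller share made the whole of the pattern, a part of it or none. Exchanged genotype labels of the female libraries cannot be told apart from a true effect, since Per2 had a ratio of 0.86 between female knockouts and controls with overlapping libraries. A knockout effect that depends on sex stays open: the interaction passed its threshold, but no value separates it from any other difference shared by the female control libraries.

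The second pattern is the lower level of stromal transcripts in the male knockouts. Stromal cells carried over in differing numbers could produce it, and such cells would keep their transcripts in 1 ratio across libraries. The first component held 57.8% of the variance of these markers, with 51.0 to 92.6% leaving out a gene (92.6% without Kdr), against a median of 60.8% for 1000 random lists of matched expression, of which 593 were as high. The random lists were compared with the 57.8% only. None were run for the 10 markers without Kdr, so they do not bear on the 92.6%. The bound set against the explanation, under 60%, was met, but it was kept open once the range leaving out a gene was known, because Kdr alone decided the value. Col1a1 was 4.2, 6.6 and 9.7 FPKM in male controls and 1.7, 2.2 and 0.9 in male knockouts. It also varied widely within 1 group: 7.08, 2.96 and 0.32 FPKM in female controls, beside 3.97, 0.95 and 1.28 in female knockouts. In female controls Col3a1 (3.12, 1.59 and 0.19) and Sparc (6.64, 2.82 and 0.44) took the same order. An effect of the knockout on stromal cells was not tested.

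The third pattern is the spread of Sumo2 within groups, which differed between the sexes by −3.36 in its knockout effect (adjusted p = 0.0342). Sumo2 was 17.9, 5.82 and 18.0 FPKM in male controls, 5.59, 39.9 and 57.5 in male knockouts, 67.5, 53.9 and 71.9 in female controls and 5.63, 7.62 and 27.4 in female knockouts. The interaction call was lost without male control replicate 2 (0.0785), male knockout replicates 2 or 3 (0.079 and 0.077), female control replicates 1, 2 or 3 (0.0602, 0.0538 and 0.0653) or female knockout replicates 1 or 2 (0.0785 and 0.0705). Reads shared with near-identical copies could add to it: 30.2% of its windows of 50 bases (303 of 1002) also lay in transcripts of 14 other genes, against a median of 0.0% and a highest share of 36.2% in 30 reference genes. That share lies between the bounds set beforehand, so it decides nothing, and no biological explanation was tested.

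Other splits of the samples were compared with the real ones. Within a sex or genotype, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 2 genes in males (10 of 10 splits as large), 6027 and 1 in females (1 of 10), 7295 and 0 for the sexes in controls (1 of 10) and 4054 and 0 for the sexes in knockouts (1 of 10). For lists they were 8 and 21 in males (5 of 10), 20 and 17 in females (1 of 10), 18 and 22 in controls (4 of 10) and 21 and 23 in knockouts (3 of 10). The other splits passed a median of 7, 12, 17 and 13 lists in the same order. Many lists thus passed the camera test without the real grouping. Over both sexes 4 of 100 splits gave as many genes as the real 4188, up to 4803, a share under 0.05, while 12 of 100 gave as many lists as the real 20, up to 24. For the interaction 5 of 100 splits gave as many genes as the real 4185, up to 4803, and 13 of 100 as many lists as the real 19, up to 21, so these shares were not under 0.05. The 14 splits that kept the female groups apart, the real one included, gave 3755 to 4803 genes over both sexes, while splits that mixed the female groups gave 1 at most there and 1 at most for the interaction. The splits with as many genes as the real ones therefore all held the real female contrast, a structure of the samples, and their share is no measure of chance for the counts of genes in either contrast.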

How the results depend on the processing

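Voom, the assigned reads as denominator, thinning to the smallest library and leaving out genes over 4-fold apart were chosen after the data were seen, and the other settings before. The count of genes in males, 0 in limma, was 4 with a pseudocount of 5, 2 with an FPKM filter of 5, 3 with rescaling to nuclear protein-coding genes, 2 with array quality weights, 2 by voom, 2 with assigned reads as the denominator and 2 after thinning. It was 0 to 1 leaving out a library. Lists that passed in males, 8, were 5 after quantile normalization, 4 with array quality weights, 5 after thinning, 0 with an estimated correlation and 0 by fry, and ranged from 5 (without male control replicate 1) to 16 (without male control replicate 3). With an estimated correlation the lists were 0 in females, 0 over both sexes, 0 for the interaction, 0 for the sexes in controls and 2 for the sexes in knockouts, and fry gave 29 for the sexes in controls. The cause of these changes was not tested. For the sexes in controls the Y-linked list was among those not passed with an estimated correlation, so that setting can miss a known difference. Voom called 6051 genes in females, 4364 over both sexes, 4551 for the interaction and 7294 and 4294 for the sexes in controls and knockouts. Over all settings, the values of named genes kept their direction and side of the threshold 4176 times in females (115 lost, 25 gained) and 4045 times in males (0 lost, 17 gained).

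Leaving out a library, the counts stayed within 1.5 times of the full ones elsewhere: 5244 to 6193 genes in females, 3628 to 4266 over both sexes, 3628 to 4039 for the interaction, 6692 to 7270 for the sexes in controls and 2987 to 4264 for those in knockouts. Among single genes and list tests past the threshold in at least 1 of the settings compared, directions reversed for the ribosomal list in males without male control replicate 3 (0.755, with 2.94e-07 without male control replicate 1), for the oxidative phosphorylation list in females after quantile normalization (0.723), and for Acp5 over both sexes after quantile normalization (−0.01). For the sexes in controls they reversed for Dbp with rescaling to nuclear protein-coding genes (0.20), for Acp5 after quantile normalization (0.25) and that rescaling (0.28), and for Mmp9 likewise (0.33 and 0.29). Quantile normalization and that rescaling also moved the median of all genes between the control groups, from 0.00 to 0.09 and 0.29, and the cause was not tested further. List medians, whether or not the list passed, changed sign under a scaling more often: 0 lists in males, 8 in females, 3 over both sexes, 6 for the interaction, 8 for the sexes in controls and 3 for those in knockouts. In females they were osteoclast differentiation (0.13, and −0.05 at its farthest), oxidative phosphorylation (0.16 and −0.04), glycolysis (0.15 and −0.01), adhesion (0.17 and −0.02), neutrophil (0.18 and −0.01), cholesterol (0.06 and −0.09), clock (0.01 and −0.14) and stem cell genes (0.03 and −0.10). Over both sexes they were adhesion (0.08 and −0.01), cholesterol (0.01 and −0.07) and oxidative phosphorylation (0.06 and −0.04). For the interaction they were adhesion (0.17 and −0.02), cholesterol (0.11 and −0.07), glycolysis (0.11 and −0.06), neutrophil (0.12 and −0.06), osteoclast differentiation (0.07 and −0.11) and oxidative phosphorylation genes (0.15 and −0.04). Between the sexes in controls they were adhesion (−0.18 and 0.14), bone resorption (−0.06 and 0.28), clock (−0.05 and 0.20), erythroid (−0.16 and 0.17), glycolysis (−0.12 and 0.20), LXR target (−0.25 and 0.04), mast cell (−0.02 and 0.23) and osteoclast differentiation genes (−0.04 and 0.28). In knockouts they were clock (−0.01 and 0.10), glycolysis (−0.07 and 0.06) and stress response genes (−0.04 and 0.11). Other settings turned the medians of macrophage markers in males (0.02 with array quality weights) and dendritic cell markers for the interaction (−0.05 with no filter), and of lists that did not pass, such as stromal (1.03 with an FPKM filter of 5) and T and NK cell markers in females (−0.06 with no filter). With the batch as a replicate block the counts were 0 in males, 6019 in females, 4153 over both sexes, 4174 for the interaction, 7274 and 4006 for the sexes in controls and knockouts. The block brought heat shock proteins past the threshold in females (0.0383), the stress response list over both sexes (0.0482) and B cell markers in controls (0.0416), and changed 2 more calls in females, Sox4 (0.0576) and Hdc (0.0272). Depth limits genes of few reads, Per2 among them, with 18 to 86 reads per library (0.204 to 0.721 FPKM), above the floor of 3 reads.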

Other observations

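The genes of this part were named by the rule fixed beforehand for at least 1 contrast or list, and their limma tests, quantile normalization and fits with no filter were planned. The choice to set them side by side here came after their values were seen, and no further test was run. Ifnb1, which encodes interferon beta, had 0 reads in each female control, with a floor of 3 reads, which is at most 0.27 FPKM in these libraries. It was 0.59 ± 0.10 FPKM in female knockouts (6 to 9 reads), at least 2.2-fold higher, and 3.62 ± 0.30 FPKM in male controls, at least 13.4-fold higher, beside 3.23 ± 0.89 in male knockouts. In both genotypes of males Irf7 (618 ± 53.7 and 628 ± 41.9 FPKM) and Ifit3 (669 ± 86.7 and 684 ± 36.5 FPKM) lay above the female knockouts (289 ± 46.6 and 195 ± 43.8 FPKM), while Mmp12 lay near them (39.8 ± 17.8 and 36.5 ± 12.8 FPKM against 30.8 ± 2.39).

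Of 15 mitochondrially encoded genes, 2 rose and 7 fell in female knockouts, 6 did not pass, and the list did not pass the camera test (adjusted p = 0.153). Those that rose were the ribosomal RNAs mt-Rnr1 (1.39) and mt-Rnr2 (0.32, a call lost after quantile normalization, adjusted p = 0.0618), and among those that fell were the mRNAs mt-Nd4 (−0.69) and mt-Nd1 (−0.46, a call lost with no filter on low values, 0.0683). Among markers of other cells, Ly6a (3.28), Kdr (2.37), Pf4 (1.15) and Cd4 (0.71) rose in female knockouts, and Siglecf (−0.58) and Ear2 (−0.79), genes of eosinophils, fell. Each gene that rose was the only one to do so in its list of stem, stromal, erythroid and megakaryocyte, or T and NK cell markers. None of these lists passed, nor did that of mast cells, basophils and eosinophils, so a change in the number of such cells was not shown. No explanation was tested for these values.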
